A study of Homo sapiens with 20 samples.

How the data were processed

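The series holds 20 Affymetrix exon arrays of total RNA from the human cell lines LP-1 (multiple myeloma) and Raji (Burkitt lymphoma), in 10 groups of 2 biological replicates per the labels. Cells were untreated at 0 h or sampled 4 and 8 h after 500 nM of a BET inhibitor or its inactive enantiomer. The labels do not name the compound. Per the labels, RNA was amplified with a whole-transcript kit, labelled with biotin and summarised with RMA in Affymetrix Expression Console on genome build hg19, with no versions given. The deposited values are log2 expression values per transcript-level probe set. RMA corrects background, applies quantile normalization to probes and summarises by median polish. The deposited array medians still differed by up to 0.263, from 5.132 to 5.395, and all values were used as deposited. Arrays carry no count of reads, so their number limits the precision of every value.

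The table has 22011 probe sets, all of which were tested without a filter. Gene symbols came from the platform's table: 14432 probe sets had 1 symbol, 2408 had several and 5171 had none, and 14404 of the first were matched by Entrez gene identifier to a RefSeq annotation of GRCh38.p14. That annotation was used for names and for the order of neighbouring genes alone, and no coordinates are given, since the deposited values were made on another build. Probe sets with several symbols or none were counted and not named.

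A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3, with 10 residual degrees of freedom and moderated variances (prior degrees of freedom 2.59). Each of 17 comparisons was tested two-sided with Benjamini-Hochberg adjustment over all probe sets, and a probe set is called higher or lower at an adjusted p under 0.05. The comparisons are BET inhibitor over inactive enantiomer, inactive enantiomer over untreated and BET inhibitor over untreated in each line at each time, the difference of the response between lines at each time and between times in each line, and untreated Raji over untreated LP-1. The p-values measure the spread between 2 biological replicates per group as the labels give them. Each probe set has 1 estimate of this spread, pooled over the 10 groups of both lines and not taken from the groups compared alone. Intervals cover 95%. No untreated or vehicle sample was taken at 4 or 8 h, so comparisons with untreated cells join compound and time in culture.

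The 25 gene lists, and 4 lists of markers of other cell types, were fixed before the data were examined, as were the comparisons, the rule for named genes and the other settings listed below. Lists were tested with limma's camera, two-sided, with its preset correlation of 0.01, against the 14232 genes measured, each by its probe set with the highest mean. The p-values were adjusted over the 100 tests of the 25 lists in the 4 comparisons of BET inhibitor over inactive enantiomer, and separately for the marker lists. Members were counted as passing over all probe sets and adjusted over the list alone. Measured sizes were: MYC network 13, MYC-activated growth genes 43, BET proteins and P-TEFb 15, histone genes 22, plasma cell genes 21, B cell and germinal centre genes 29, HLA class II genes 7, G1/S and replication genes 29, G2/M genes 25, CDK inhibitors and antiproliferative genes 19, BCL2 family 17, immediate early genes 23, NF-kB targets 27, interferon-stimulated genes 31, ATF4 targets 24, ER chaperones and unfolded protein response 22, sterol synthesis genes 18, nucleotide synthesis genes 21, glycolysis genes 19, lysosome and autophagy genes 26, p53 targets 23, ribosomal protein genes 15, oxidative phosphorylation genes 26, genes reported lowered by BET inhibition in blood cancer lines 23 and genes reported raised by BET inhibition 13. Both last lists come from general knowledge, and the lists overlap. Marker lists held 14 genes of T and NK cells, 10 of myeloid cells, 13 of epithelial cells and fibroblasts and 3 of erythroid cells.

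Genes are named by these rules: MYC, HEXIM1, BRD2, BRD3 and IRF4 always; the 6 largest called falls and rises per comparison of BET inhibitor over inactive enantiomer among probe sets with 1 symbol and both treated arrays beyond both control arrays; up to 4 members of each list with the smallest p in each line; the 4 largest calls each way for inactive enantiomer over untreated; the 6 largest each way for differences between lines and times; and the 8 largest each way between the untreated lines. Genes on the Y chromosome and XIST were not named, and a further gene is not reported here. Genes named in the part on other observations outside these rules (OR2B2, HFE, BTN3A2, RRP1B, SRXN1, UGDH and genes called in all 4 comparisons) were chosen after their values were seen.

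Other settings chosen then were leaving out the 7337 probe sets with the lowest mean, quantile normalization of the deposited values, centring each array on its median, moderated variances with an intensity trend and robust estimation, the replicate number as a block within each line, only the 10 arrays of the line concerned, an estimated correlation in camera, and leaving out each array in turn. Where an omission left 1 array in a group, that array was taken to vary like the other groups. Leaving out both arrays that stood apart was added after the data were seen.

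The procedure was tested on simulated data with the probe sets drawn independently and 200 of them changed. Of probe sets changed 1.5-fold it recovered between 7.46% and 22.4%, of those changed 2-fold between 43.3% and 61.2%, and of those changed 4-fold between 80.3% and 92.4%, across the 4 comparisons of BET inhibitor over inactive enantiomer. Between 1.02% and 9.52% of the calls were unchanged probe sets. With no change simulated, 0, 0, 1 and 0 probe sets were called in the comparisons of inactive enantiomer over untreated. Camera recovered 5 of 5 lists shifted by 0.5. As the probe sets were drawn independently, this does not show how camera performs on lists of correlated genes.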

Results

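Gene expression was measured on 20 exon arrays from a pair of human blood cancer cell lines. LP-1 is a multiple myeloma line, a cancer of plasma cells, and Raji is a Burkitt lymphoma line, a B cell cancer in which MYC is driven by an immunoglobulin locus. Each line was left untreated (0 h) or given 500 nM of an inhibitor of BET proteins, the bromodomain proteins that bind acetylated histones. Control cells received the same dose of its inactive enantiomer, the mirror-image form, and both compounds were sampled after 4 and 8 h. This gave 10 groups of 2 biological replicates, and the number of arrays limits the precision of every value below. Array medians lay between 5.13 and 5.39 log2 units. Pearson's r between replicate arrays, across probe sets that are not independent of each other, was 0.973 to 0.989. Unless another error is named, changes are log2 fold changes with their standard error (n = 2 arrays per group) and a p adjusted over the 22011 probe sets.

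The comparison at the centre of the design set the BET inhibitor against its inactive enantiomer at the same dose and time, and so asked which genes differ between the active and the inactive form. MYC, the proto-oncogene that drives growth in both cancers, was lower with the inhibitor in both lines at both times. In LP-1 it dropped from 9.59 ± 0.01 to 7.28 ± 0.14 at 4 h (mean ± SD of log2 values, n = 2), a 4.94-fold fall (adjusted p = 5.25e-05). At 8 h it changed by -1.85 ± 0.16 (adjusted p = 7.19e-05). In Raji it fell by 1.41 ± 0.16 at 4 h (2.65-fold, adjusted p = 0.00129) and by 1.40 ± 0.16 at 8 h (adjusted p = 0.00101). HEXIM1, an inhibitor of the elongation factor P-TEFb that is commonly used as a marker of BET inhibition, rose by 1.04 ± 0.14 and 1.45 ± 0.14 in LP-1 and by 1.93 ± 0.14 and 1.90 ± 0.14 in Raji at 4 and 8 h (adjusted p = 0.00269, 0.000108, 0.000101 and 0.000125). BRD2, which encodes a BET protein itself, rose by 0.49 ± 0.11 and 0.98 ± 0.11 in LP-1 and by 0.49 ± 0.11 in Raji at 4 h (adjusted p = 0.0428, 0.000438 and 0.0484). At 8 h in Raji its change was 0.41 ± 0.11 (adjusted p = 0.0996). The rises at 4 h lost their call without any 1 of the arrays compared (highest adjusted p 0.344 in LP-1 without 1 array and 0.326 in Raji). BRD3 and IRF4, a transcription factor on which myeloma cells depend, passed the test in none of the 4 comparisons. For IRF4 the 95% interval was -0.54 to 0.29 in LP-1 at 4 h and -0.40 to 0.43 in Raji at 8 h. Untreated Raji lay below untreated LP-1 in IRF4 (-5.67 ± 0.19). No test against background was made, so a fall of IRF4 in Raji could have gone unseen. The falls of MYC and the rises of HEXIM1 kept their calls without each array in turn.

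**Figure D1:**
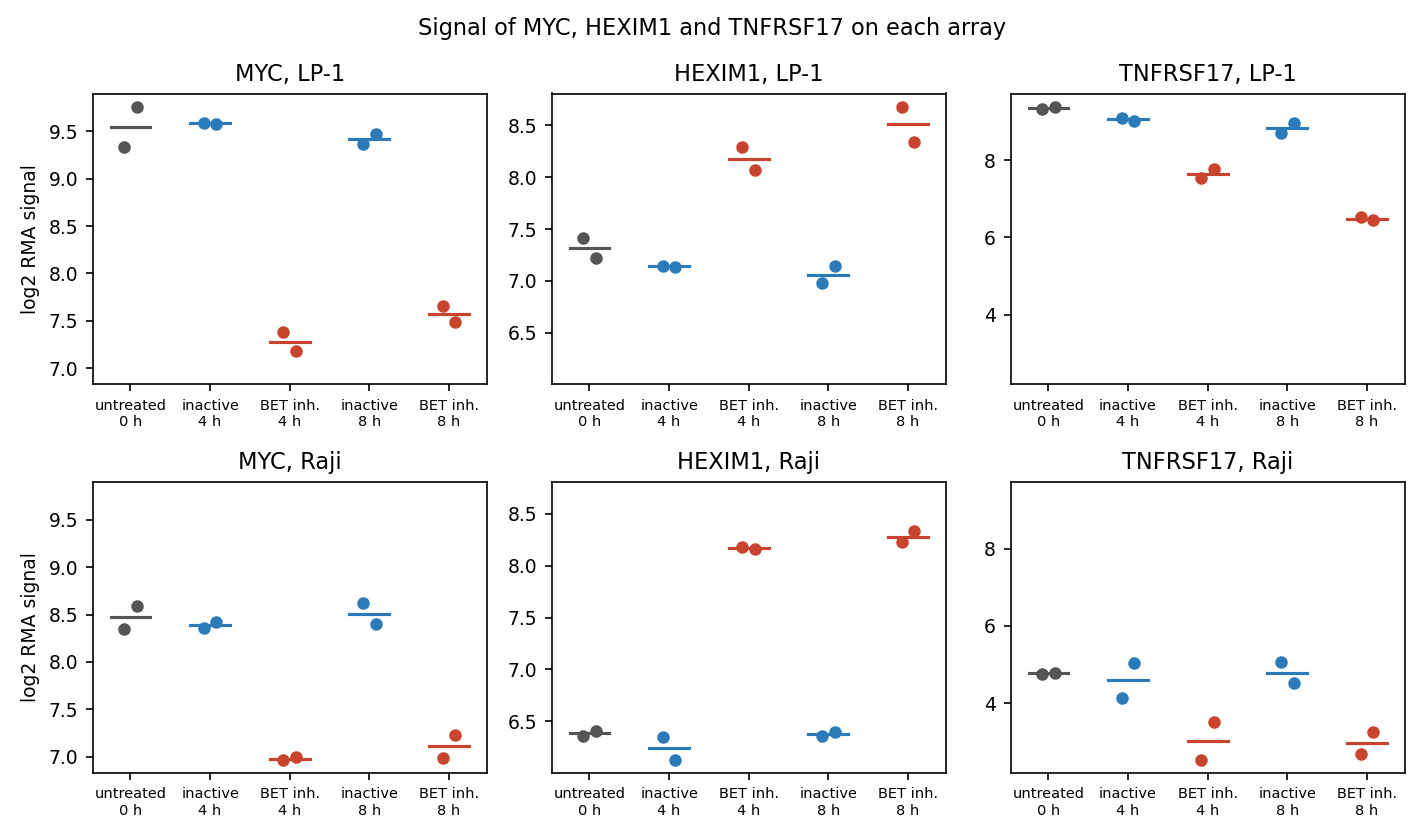
Level of MYC, HEXIM1 and TNFRSF17 on each array in LP-1 and Raji (log2 RMA value, y axis) by compound and time (x axis), with each group's mean as a bar. MYC and TNFRSF17 sit lower and HEXIM1 higher on both BET inhibitor arrays than on both inactive enantiomer arrays of the same line and time.

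In LP-1 at 4 h the largest fall was that of CCR1, a chemokine receptor gene, by 3.38 ± 0.39 (adjusted p = 0.00109). MYC came next, and RGS1, a regulator of G protein signalling, fell by 2.28 ± 0.24 (adjusted p = 0.000549). SPRY1, ANXA1 and GPR19 fell by 2.19, 2.17 and 2.11. The largest rises were in OR2B6, an olfactory receptor gene (3.09 ± 0.51, adjusted p = 0.00832), the orphan receptor gene GPR50 (2.37 ± 0.33), the histone genes H2AC11 (2.18 ± 0.22), H2BC21 (2.17 ± 0.35) and H2BC11 (1.85 ± 0.32), and ATP1B1, a subunit of the sodium pump (2.09 ± 0.22). In all, 502 probe sets passed (83 higher, 419 lower). Of the 25 gene lists, 9 shifted against all other genes, 4 up and 5 down.

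The list of histone genes shifted up in LP-1 at 4 h (adjusted p = 4.24e-11). Of 22 measured, 2 rose (H2BC11 and H2BC21), none fell and 20 did not pass, against 11 higher when adjusted over the list alone. Immediate early genes, which respond first to a stimulus, shifted up (adjusted p = 3.2e-08). EGR1 (1.83 ± 0.17), ZFP36 (1.33 ± 0.15) and ATF3 (0.77 ± 0.12) were higher, with 20 of 23 not passing (7 higher adjusted over the list alone). CDK inhibitors and antiproliferative genes shifted up (adjusted p = 2.16e-05), with 4 of 19 higher, among them CDKN1A, which encodes the cell cycle inhibitor p21 (1.48 ± 0.28), TXNIP (1.09 ± 0.17) and TOB1 (0.80 ± 0.14), and 6 higher adjusted over the list alone. Genes reported raised by BET inhibition shifted up (adjusted p = 8.81e-13). In that list 7 of 13 rose, including SAT1, an enzyme of polyamine breakdown (1.78 ± 0.17), 5 did not pass, and HMOX1 fell by 2.02 ± 0.29 (11 higher and 1 lower adjusted over the list alone). Genes reported lowered by BET inhibition in blood cancer lines shifted down (adjusted p = 0.000165), with 6 of 23 lower, among them MYB (-0.99 ± 0.19), BCL2 (-0.86 ± 0.19) and E2F2 (-0.82 ± 0.12), and 7 lower adjusted over the list alone. These 5 lists kept their shift with an estimated correlation (highest adjusted p 0.0493).

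MYC-activated growth genes, which serve ribosome assembly and biosynthesis, shifted down in LP-1 at 4 h (adjusted p = 4.77e-07, but adjusted p = 0.162 with an estimated correlation). Of 43 measured, 6 fell, among them PPRC1 (-1.21 ± 0.13) and NOP16 (-1.07 ± 0.21), and 37 did not pass, against 12 lower adjusted over the list alone. Plasma cell genes shifted down (adjusted p = 0.00048, adjusted p = 0.162 with an estimated correlation), with only TNFRSF17, the plasma cell surface receptor BCMA, passing of 21 (-1.40 ± 0.32) and 6 lower adjusted over the list alone. The call of TNFRSF17 at 4 h was lost without any 1 of the 4 arrays compared. G2/M genes (adjusted p = 0.0469) and nucleotide synthesis genes (adjusted p = 0.0487) shifted down as lists, with 0 of 25 and 1 of 21 genes passing by limma (UMPS, -0.60 ± 0.14), and 0 and 3 lower adjusted over the list alone. With an estimated correlation these last lists had adjusted p = 0.66 and adjusted p = 0.668. The count of 502 moved with every array: it was 186 without BET inhibitor replicate 1, 971 without BET inhibitor replicate 2, 78 without inactive replicate 1 and 64 without inactive replicate 2. Of the 38 named genes that passed, 22, 33, 16 and 15 kept their call in these fits. BET inhibitor replicate 1 stood apart, with a 75th percentile of 6.80 against 7.03 on its replicate. The share of higher calls was 16.5% as deposited, 26.4% with each array centred on its median and 33% after quantile normalization (126 higher, 256 lower), and 37.6% and 9.27% without BET inhibitor replicates 1 and 2.

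In LP-1 at 8 h CCR1 fell by 3.74 ± 0.39 (adjusted p = 0.000223), CXCL10, a chemokine induced by interferon, by 2.49 ± 0.29, and PECAM1, an adhesion molecule, by 2.44 ± 0.27. TNFRSF17 fell by 2.37 ± 0.32, EDNRB, an endothelin receptor, by 2.15 ± 0.23 and P2RY10 by 2.11 ± 0.29. ATP1B1 rose by 3.17 ± 0.22 (adjusted p = 1.81e-05), OR2B6 by 3.12 ± 0.51 and CEMIP2, a surface hyaluronidase, by 2.97 ± 0.20. FGD6 rose by 2.82 ± 0.26, and the histone genes H2BC5 and H2BC11 by 3.09 ± 0.57 and 2.96 ± 0.32. A total of 1262 probe sets passed (828 higher, 434 lower), and 11 lists shifted, 8 up and 3 down.

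MYC-activated growth genes shifted down in LP-1 at 8 h (adjusted p = 6.13e-19), and this shift held with an estimated correlation (adjusted p = 0.0249). Of 43 measured, 18 fell and 25 did not pass (25 lower adjusted over the list alone), among them NOP16 (-1.67 ± 0.21), PRMT3 (-1.02 ± 0.14), TMEM97 (-0.85 ± 0.13) and CAD, the first enzyme of pyrimidine synthesis (-0.58 ± 0.15). Genes reported raised by BET inhibition shifted up (adjusted p = 1.54e-11, 10 of 13 higher, with HMOX1 lower by log2 -1.54 ± 0.29 and 11 higher and 1 lower adjusted over the list alone). Genes reported lowered shifted down (adjusted p = 1.94e-05, 5 of 23 lower, including IKZF3, a B lineage transcription factor, at -1.48 ± 0.22, with 8 lower and 1 higher adjusted over the list alone). CDK inhibitors and antiproliferative genes shifted up (adjusted p = 2.45e-05), with 7 of 19 higher, among them TXNIP (1.98 ± 0.17), CDKN2D (1.37 ± 0.21), KLF6 (1.29 ± 0.21) and CDKN1A (1.04 ± 0.28), and 9 higher adjusted over the list alone. These 3 lists also kept their shift with an estimated correlation (highest adjusted p 0.0493).

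Plasma cell genes shifted down in LP-1 at 8 h (adjusted p = 2.56e-06, adjusted p = 0.0658 with an estimated correlation). Of these, 5 of 21 fell, among them SLAMF7, a surface receptor of plasma cells (-1.60 ± 0.18), POU2AF1, a coactivator of immunoglobulin genes (-0.63 ± 0.12), and FKBP11 (-0.55 ± 0.11), with 8 lower adjusted over the list alone. Histone genes shifted up with 6 of 22 higher (adjusted p = 9.08e-06, adjusted p = 0.162 with an estimated correlation), including H2BC21 (2.47 ± 0.35) and H4C16 (2.36 ± 0.40), and 11 higher adjusted over the list alone. Lysosome and autophagy genes shifted up with 4 of 26 higher (adjusted p = 0.000186, adjusted p = 0.179 with an estimated correlation). They were NEU1 (1.08 ± 0.20), MAP1LC3B (0.97 ± 0.17), NPC1 (0.97 ± 0.16) and CTSB (0.81 ± 0.21), with 11 higher adjusted over the list alone. For p53 targets 8 of 23 rose, among them PLK2 (1.38 ± 0.27) and POLH (1.04 ± 0.19). MDM2, which encodes the negative regulator of p53, fell by 0.74 ± 0.18 (list adjusted p = 0.0305, adjusted p = 0.344 with an estimated correlation, 11 higher and 3 lower adjusted over the list alone). Immediate early genes had 5 of 23 higher, such as DUSP1 (1.37 ± 0.28) and EGR1 (1.16 ± 0.17), with 7 adjusted over the list alone (list adjusted p = 0.00403, adjusted p = 0.272 with an estimated correlation).

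G2/M genes, which serve mitosis, had 3 of 25 higher in LP-1 at 8 h, CDC25C (1.18 ± 0.28), NEK2 (0.62 ± 0.13) and PTTG1 (0.60 ± 0.15), with 5 higher adjusted over the list alone (list adjusted p = 0.00862, adjusted p = 0.522 with an estimated correlation). BET proteins and P-TEFb had 4 of 15 higher, including AFF4 of the super elongation complex (0.74 ± 0.14), and 1 lower, MLLT3 (-0.76 ± 0.18), with 5 higher and 1 lower adjusted over the list alone (list adjusted p = 0.0382, adjusted p = 0.198 with an estimated correlation). The count of 1262 was 509 without BET inhibitor replicate 1, 485 without inactive replicate 1 and 592 without inactive replicate 2. Of the 70 named genes that passed, 35 kept their call without each array in turn, among them CCR1, ATP1B1, CEMIP2, TNFRSF17, NOP16, TXNIP and SLAMF7. The share of higher calls was 65.6% as deposited and 49.9% with each array centred on its median.

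In Raji at 4 h PTAFR, the receptor of platelet-activating factor, fell by 2.81 ± 0.53 (7.02-fold, adjusted p = 0.0196), CHRNA6 by 1.89 ± 0.30 and CD180, a Toll-like receptor relative of B cells, by 1.69 ± 0.18 (adjusted p = 0.00102). ALOX12 fell by 1.67 ± 0.27, GPR183, which guides B cells in lymphoid tissue, by 1.64 ± 0.24 and CXCL10 by 1.63 ± 0.29. OR2B6 rose by 3.03 ± 0.51 (adjusted p = 0.0124), ZNF627 by 2.46 ± 0.36 and H2BC11 by 2.29 ± 0.32. TAS2R19 rose by 2.17 ± 0.47, ERP27, an endoplasmic reticulum protein, by 2.11 ± 0.32 and SLFN5 by 2.08 ± 0.21. There were 391 probe sets that passed (316 higher, 75 lower), and 12 lists shifted, 8 up and 4 down. The share of higher calls was 80.8% as deposited, 73.2% with each array centred on its median and 61.2% after quantile normalization (278 higher, 176 lower).

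Genes reported raised by BET inhibition shifted up in Raji at 4 h (adjusted p = 1.26e-09), with 5 of 13 higher, including TXNIP (1.23 ± 0.17) and SAT1 (1.30 ± 0.17), and 9 adjusted over the list alone. Genes reported lowered shifted down (adjusted p = 1.69e-08), with 5 of 23 lower, including MYB (-1.02 ± 0.19), and 8 adjusted over the list alone. Both held with an estimated correlation (adjusted p = 0.00415 and 0.0094), and the other 10 shifts in Raji at 4 h did not. Sterol synthesis genes shifted up (adjusted p = 7.67e-06, adjusted p = 0.138 with an estimated correlation), with INSIG1 (1.03 ± 0.17) and IDI1 (0.92 ± 0.18) higher of 18 and 7 higher adjusted over the list alone. Lysosome and autophagy genes shifted up (adjusted p = 1.11e-05, adjusted p = 0.135 with an estimated correlation), with NEU1 (1.06 ± 0.20), NPC1 (0.90 ± 0.16) and MAP1LC3B (0.82 ± 0.17) higher of 26, and 8 higher and 1 lower adjusted over the list alone. Histone genes shifted up (adjusted p = 1.26e-05, adjusted p = 0.166 with an estimated correlation), with H2BC11 and H2AC6 (0.87 ± 0.14) higher of 22 and 5 adjusted over the list alone. The chaperones and unfolded protein response genes of the endoplasmic reticulum (ER) shifted up (adjusted p = 9.6e-05, adjusted p = 0.192 with an estimated correlation), with the oxidase gene ERO1B higher (1.08 ± 0.18), 21 of 22 not passing and 5 higher adjusted over the list alone.

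BET proteins and P-TEFb shifted up in Raji at 4 h (adjusted p = 0.00103, adjusted p = 0.0646 with an estimated correlation), with HEXIM1, BRD2 and the cyclin gene CCNT1 (0.84 ± 0.17) higher of 15 and 5 adjusted over the list alone. CDK inhibitors and antiproliferative genes shifted up (adjusted p = 0.00738, adjusted p = 0.169 with an estimated correlation), with TOB1 (1.14 ± 0.14) and TXNIP higher of 19 and 4 adjusted over the list alone. MYC-activated growth genes shifted down by a median of -0.13 (adjusted p = 0.000578, adjusted p = 0.344 with an estimated correlation), with 0 of 43 genes passing by limma and 0 adjusted over the list alone. Oxidative phosphorylation genes shifted up by a median of 0.15 (adjusted p = 0.0214, adjusted p = 0.373 with an estimated correlation), with 0 of 26 passing and 1 higher adjusted over the list alone. B cell genes shifted down (adjusted p = 0.0166, adjusted p = 0.22 with an estimated correlation), with BLNK, an adaptor of B cell receptor signalling (-0.81 ± 0.17), the 1 gene of 29 to pass in either count. NF-kB targets shifted down (adjusted p = 0.0172, adjusted p = 0.4 with an estimated correlation), with CXCL10 lower of 27, and 4 lower and 1 higher adjusted over the list alone. The count of 391 fell to 116 without BET inhibitor replicate 1, 27 without BET inhibitor replicate 2, 111 without inactive replicate 1, which stood apart on its own scale (75th percentile 6.75) and 154 without inactive replicate 2. Of the 35 named genes that passed, 5 kept their call without each array in turn (MYC, HEXIM1, CD180, SLFN5 and PRDM1).

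In Raji at 8 h PTAFR fell by 3.23 ± 0.53 (9.36-fold, adjusted p = 0.00992), SPARCL1, an extracellular matrix protein gene, by 2.40 ± 0.19 (adjusted p = 0.000154), and SCIMP, an adaptor protein gene of B cells, by 2.18 ± 0.27. BANK1, a B cell scaffold protein gene, fell by 2.16 ± 0.24, TUBB2B by 2.06 ± 0.44 and DEPTOR, an inhibitor of mTOR, by 1.91 ± 0.20. H2BC11 rose from 3.62 ± 0.75 to 5.92 ± 0.07 (mean ± SD, n = 2, adjusted p = 0.00497) and OR2B6 rose by 2.24 ± 0.51 (adjusted p = 0.0452), both from control levels below the 25th percentile of their arrays and not tested against background. GPR22 rose by 1.80 ± 0.38, SESN3, a stress-induced inhibitor of mTORC1, by 1.75 ± 0.16 and SLFN5 by 1.59 ± 0.21. The test passed 414 probe sets (182 higher, 232 lower), and 14 lists shifted, 6 up and 8 down.

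ATF4 targets, which include amino acid synthesis and transport genes, shifted down in Raji at 8 h (adjusted p = 1.93e-09). Of its genes 6 of 24 fell, with 11 adjusted over the list alone. Among them were PSAT1, an enzyme of serine synthesis (-1.03 ± 0.21), the amino acid transporter SLC7A5 (-0.93 ± 0.10) and the tRNA synthetase genes WARS1 (-0.89 ± 0.13) and AARS1 (-0.75 ± 0.14). B cell and germinal centre genes shifted down (adjusted p = 4.41e-08), with TCL1A (-1.45 ± 0.24), BLNK (-0.93 ± 0.17) and PAX5, the transcription factor of B cell identity (-0.80 ± 0.17), lower of 29 and 13 adjusted over the list alone. Genes reported raised by BET inhibition shifted up (adjusted p = 6.45e-12), with 4 of 13 higher and 9 adjusted over the list alone. Genes reported lowered shifted down (adjusted p = 2.2e-08), with 4 of 23 lower, including CD180 (-1.82 ± 0.18), and 7 adjusted over the list alone. All 4 of these lists held with an estimated correlation (highest adjusted p 0.0227), and the other 10 shifts did not. MYC-activated growth genes shifted down (adjusted p = 7.99e-11, adjusted p = 0.0707 with an estimated correlation), with HSPE1 (-1.02 ± 0.21), TFB2M (-0.88 ± 0.18), PPRC1 (-0.57 ± 0.13) and TCOF1 (-0.52 ± 0.10) lower of 43 and 13 adjusted over the list alone. Histone genes shifted up (adjusted p = 6.44e-08, adjusted p = 0.097 with an estimated correlation), with H2BC11 higher of 22 and 9 adjusted over the list alone.

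ER chaperones and unfolded protein response genes shifted down in Raji at 8 h (adjusted p = 6.16e-06, adjusted p = 0.146 with an estimated correlation), with SDF2L1 (-0.99 ± 0.15) and HERPUD1 (-0.70 ± 0.13) lower of 22, and 7 lower and 1 higher adjusted over the list alone. Plasma cell genes shifted down (adjusted p = 0.00214, adjusted p = 0.201 with an estimated correlation), with 4 of 21 lower and 5 adjusted over the list alone. They were TNFRSF17 (-1.82 ± 0.32), PRDM1, which directs plasma cell differentiation (-1.43 ± 0.15), SLAMF7 (-1.26 ± 0.18) and FKBP11 (-1.04 ± 0.11). NF-kB targets shifted down (adjusted p = 0.00104, adjusted p = 0.22 with an estimated correlation), with CXCL10 (-1.50 ± 0.29), CD80, a costimulatory molecule (-0.93 ± 0.21), and IL10 (-0.78 ± 0.17) lower of 27, and 8 lower and 1 higher adjusted over the list alone. Nucleotide synthesis genes shifted down (adjusted p = 0.00754, adjusted p = 0.535 with an estimated correlation), with the CTP synthase gene CTPS2 lower (-1.49 ± 0.15) of 21, and 2 lower and 1 higher adjusted over the list alone. Lysosome and autophagy genes shifted up (adjusted p = 0.000183, adjusted p = 0.179 with an estimated correlation), with 4 of 26 higher, including GLA (0.67 ± 0.14), and 8 higher and 3 lower adjusted over the list alone. Sterol synthesis genes also shifted up (adjusted p = 0.0214, adjusted p = 0.462 with an estimated correlation), with INSIG1 the 1 of 18 to pass (0.95 ± 0.17) and 4 higher and 1 lower adjusted over the list alone. CDK inhibitors and antiproliferative genes shifted up (adjusted p = 0.00134, adjusted p = 0.122 with an estimated correlation), with CDKN1B, which encodes the cell cycle inhibitor p27 (1.37 ± 0.22), TXNIP (1.03 ± 0.17) and TOB1 (0.75 ± 0.14) higher of 19 and 4 adjusted over the list alone. BET proteins and P-TEFb shifted up (adjusted p = 0.000648, adjusted p = 0.0569 with an estimated correlation), with HEXIM1 the 1 of 15 to pass and 5 higher adjusted over the list alone. The count of 414 was 108 and 100 without BET inhibitor replicates 1 and 2, and 145 and 118 without inactive replicates 1 and 2. Of the 47 named genes that passed, 15 kept their call without each array in turn, among them SPARCL1, SCIMP, BANK1, DEPTOR, CD180, SLC7A5, CTPS2 and PRDM1.

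**Figure D2:**
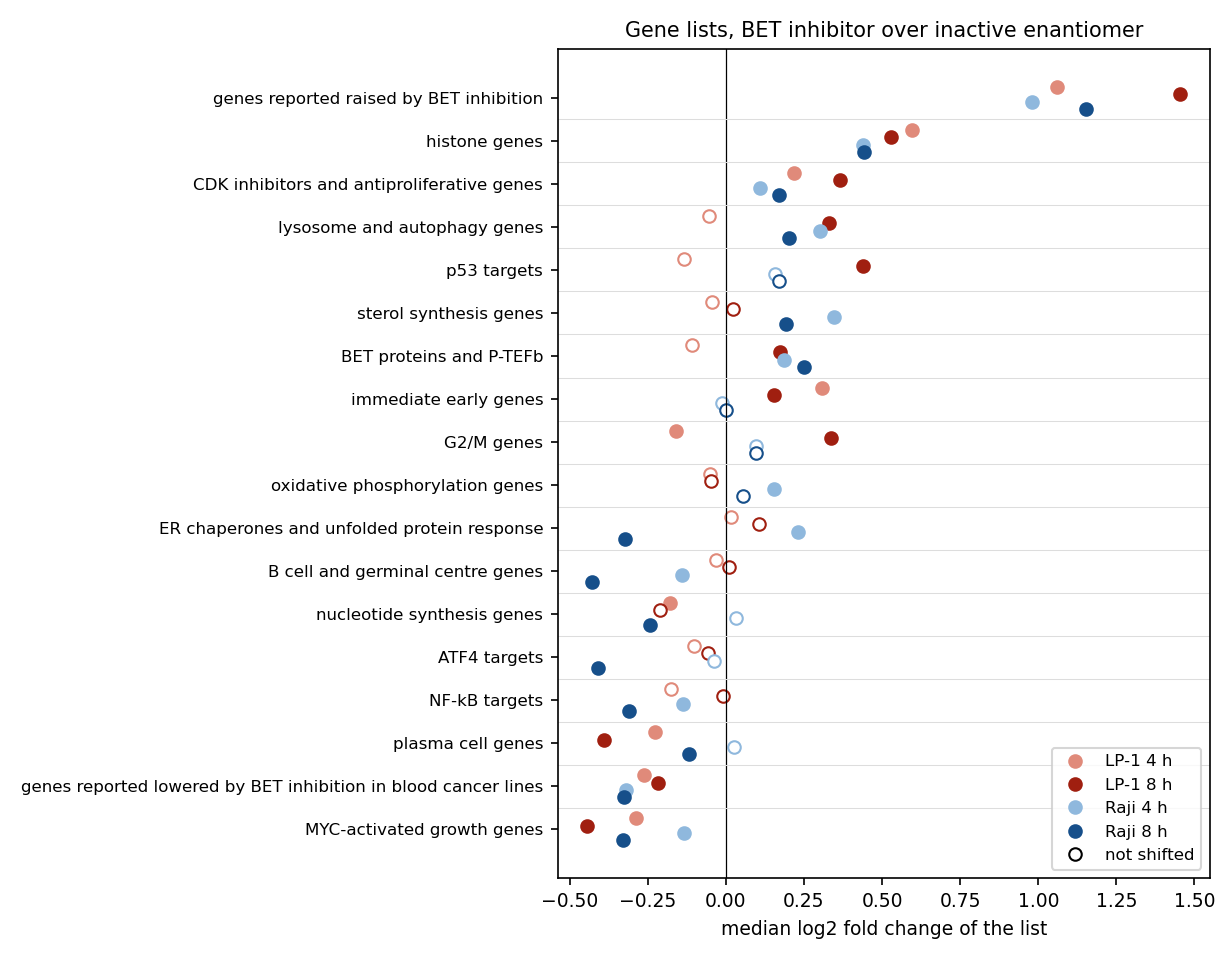
Median log2 fold change of each gene list that shifted in at least 1 comparison (x axis), BET inhibitor over inactive enantiomer, for LP-1 and Raji at 4 and 8 h (colours). Filled points are lists that shifted by camera with its preset correlation, and open points did not; genes reported raised by BET inhibition, at medians of 0.98 to 1.45, lie furthest to the right.

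Among the 25 lists, 5 shifted in all 4 comparisons: MYC-activated growth genes and genes reported lowered by BET inhibition down, and histone genes, CDK inhibitors and antiproliferative genes, and genes reported raised by BET inhibition up. With an estimated correlation the lists of genes reported raised and lowered held in all 4, while MYC-activated growth genes held in LP-1 at 8 h alone, histone genes in LP-1 at 4 h alone, and CDK inhibitors and antiproliferative genes in LP-1 alone. The lists of the MYC network (MYC itself and its partners), HLA class II, G1/S and replication, BCL2 family, interferon-stimulated, glycolysis and ribosomal protein genes shifted in none of the 4 (camera, lowest adjusted p 0.0793, for interferon-stimulated genes). Single members of these lists still passed, except for ribosomal protein genes, with 0 of 15 in each comparison. CIITA, the master regulator of HLA class II genes, fell by 1.01 ± 0.10 and 1.35 ± 0.10 in LP-1 and by 0.50 ± 0.10 and 0.62 ± 0.10 in Raji at 4 and 8 h. It stayed called in all 4 comparisons in 9 of 16 omissions of an array. In LP-1 at 8 h BNIP3L of the BCL2 family rose by 0.81 ± 0.17, after a fall of BCL2 at 4 h. Of glycolysis genes PKM rose by 0.56 ± 0.12, while HK2 and TPI1 fell by 0.81 ± 0.17 and 1.48 ± 0.39. Among interferon-stimulated genes IRF9, a signalling factor, rose by 0.74 ± 0.13 and SAMD9L fell by 1.35 ± 0.20. CCNE2 of the G1/S list rose by 0.66 ± 0.18, and E2F2 of that list had fallen at 4 h. Of these calls at 8 h, those of IRF9 and SAMD9L were kept without each array in turn, and those of CCNE2 and TPI1 were lost without any 1 of the 4 arrays. Marker lists of T and NK cells, myeloid cells, epithelial cells and fibroblasts, and erythroid cells shifted in none of the comparisons (lowest adjusted p 0.503). Of their genes TRAT1 alone passed, lower in LP-1 by log2 -0.95 ± 0.22 at 4 h and -1.44 ± 0.22 at 8 h. The median, the mean and the test had the same sign in all 46 list tests that shifted, and their medians kept that sign under both rescalings of the arrays. Signs differed in 22 of the 54 that did not shift, among them HLA class II genes in LP-1 at 8 h (median 0.03, mean -0.18). Under either rescaling the number of shifted lists was 7 in LP-1 at 4 h, against 9 as deposited. It stayed at 11 in LP-1 at 8 h, 12 in Raji at 4 h and 14 in Raji at 8 h.

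Both lines shared part of the response. In all 4 comparisons 31 probe sets passed in one direction, 17 higher and 14 lower, of which 13 and 14 carried a single symbol. MYC, HEXIM1, TNFRSF17, CIITA, H2BC11, OR2B6, TXNIP, TOB1, SAT1, INSIG1 and MYB, the hematopoietic transcription factor, belong to this set. In most omissions of 1 array, INSIG1, TNFRSF17, MYB and OR2B6 were no longer called in all 4. Of the 31, MYC and HEXIM1 were among those still called in all 4 without each array in turn. The number still called was 10 without either LP-1 inactive array at 4 h, 19 without LP-1 BET inhibitor replicate 1 at 4 h, 16 and 9 without Raji BET inhibitor replicates 1 and 2 at 4 h, and 19 without either Raji inactive array at 4 h. It was 12 and 11 without Raji BET inhibitor replicates 1 and 2 at 8 h and 13 and 15 without Raji inactive replicates 1 and 2 at 8 h. At 8 h, 103 probe sets were higher in both lines (6.85 expected by chance if calls were independent) and 73 lower in both (4.57 expected), with 4 in opposite directions. Across all 22011 probe sets, which are not independent replicates, Pearson's r between the changes of the lines was 0.251 (Spearman's rho 0.283). At 4 h, 30 were higher in both (1.19 expected), 23 lower in both (1.43 expected) and 3 opposite, with r = 0.03 (rho = -0.027). This r at 4 h changed sign to -0.041 without LP-1 BET inhibitor replicate 2 and to -0.035 without Raji BET inhibitor replicate 1.

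**Figure D3:**
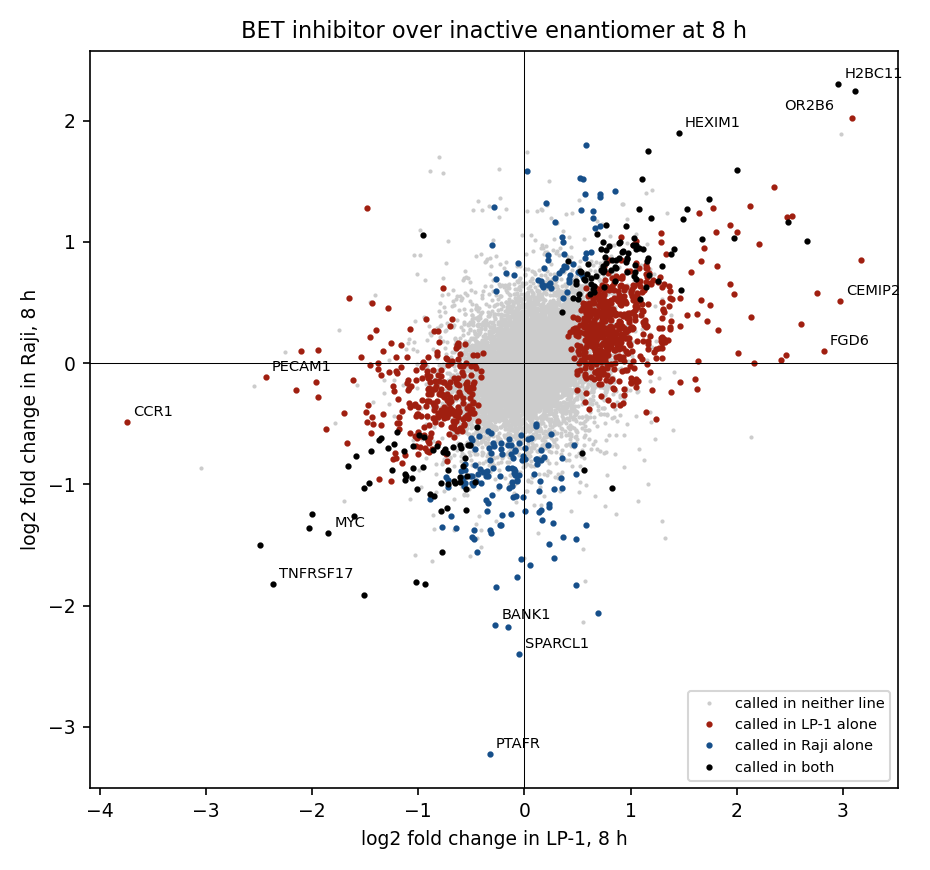
Log2 fold change of BET inhibitor over inactive enantiomer at 8 h in LP-1 (x axis) and Raji (y axis), with 1 point per probe set, coloured by the lines in which it passed. MYC (-1.85 and -1.40) and HEXIM1 (1.45 and 1.90) lie in the quadrants shared by both lines, and PECAM1 (-2.44 in LP-1) lies along the LP-1 axis.

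Whether the lines responded differently was tested as the difference between their changes, Raji minus LP-1. The lines were grown in different media, so line and medium cannot be told apart in this test. At 4 h 25 probe sets passed, 24 of them relatively higher in Raji. This split moved with scaling: 11 were higher and 5 lower after quantile normalization, and 4 higher and 0 lower with each array centred on its median. NFIL3, a transcription factor of lymphocytes, rose by 1.25 ± 0.22 in Raji and fell by 1.38 ± 0.22 in LP-1 (difference 2.63 ± 0.31, adjusted p = 0.0168). RGL1, TUBD1, IL12A and LRP2BP fell in LP-1 by 1.45 ± 0.20, 1.77 ± 0.16, 1.51 ± 0.17 and 1.09 ± 0.19 (differences 2.26 ± 0.28, 2.23 ± 0.23, 1.61 ± 0.24 and 1.67 ± 0.26). CA13, a carbonic anhydrase, rose in Raji by 1.12 ± 0.19 (difference 1.89 ± 0.27), and the stress-induced factor ATF3 rose in LP-1 (difference -1.05 ± 0.18). At 8 h 54 passed, 20 relatively higher and 34 relatively lower in Raji. CCR1 (difference 3.25 ± 0.55), PECAM1 (2.32 ± 0.38), SELPLG, the selectin ligand (2.19 ± 0.20), EDNRB (1.93 ± 0.32) and MLKL, which carries out necroptosis (1.81 ± 0.30), fell in LP-1. The myeloma surface receptor gene GPRC5D fell by 0.95 ± 0.22 in LP-1 and rose by 1.06 ± 0.22 in Raji (difference 2.01 ± 0.32, adjusted p = 0.0242). FGD6, CEMIP2, ATP1B1, TUFT1 and PAG1 rose in LP-1 by 2.17 to 3.17 (differences -2.72 ± 0.36, -2.46 ± 0.28, -2.32 ± 0.31, -2.28 ± 0.31 and -2.16 ± 0.33). SPARCL1 fell in Raji (difference -2.34 ± 0.27, adjusted p = 0.0054). A gene weakly expressed in 1 of the lines could fall little there, and levels were not tested against background. For MYC the difference was 0.90 ± 0.22 at 4 h (adjusted p = 0.104) and 0.44 ± 0.22 at 8 h (adjusted p = 0.588). For HEXIM1 it was 0.89 ± 0.20 (adjusted p = 0.0893) and 0.45 ± 0.20 (adjusted p = 0.518).

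The counts of differences between lines rested on single arrays. At 4 h the 25 became 8 and 484 without LP-1 BET inhibitor replicates 1 and 2, 1 and 0 without LP-1 inactive replicates 1 and 2, 2 without either Raji BET inhibitor replicate, and 11 and 15 without Raji inactive replicates 1 and 2. At 8 h the 54 became 31 and 131 without LP-1 BET inhibitor replicates 1 and 2, and 27 and 26 without LP-1 inactive replicates 1 and 2. It was 25 and 17 without Raji BET inhibitor replicates 1 and 2, and 21 without either Raji inactive replicate. None of the 7 genes named at 4 h kept its call without each array in turn, while 5 of the 12 at 8 h did (ATP1B1, CEMIP2, FGD6, SELPLG and SPARCL1). Centring each array moved the median difference between lines at 4 h by -0.11, and 4 probe sets then passed.

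A change of the response between 4 and 8 h was tested in each line as the 8 h change minus the 4 h change. By limma 0 probe sets passed in LP-1 (2901 at an unadjusted p under 0.05) and 0 in Raji (1257 at an unadjusted p under 0.05). MYC differed by 0.46 (95% interval -0.02 to 0.93) in LP-1 and by 0.00 (-0.47 to 0.48) in Raji, and BRD2 by 0.49 in LP-1 (0.14 to 0.84, adjusted p = 0.208). Leaving out LP-1 BET inhibitor replicate 2 at 4 h gave 560 passing probe sets, and leaving out LP-1 BET inhibitor replicate 2 at 8 h gave 85. Counts without BET inhibitor replicate 1 at 4 h and without inactive replicates 1 and 2 at 8 h were 1, 2 and 4. In Raji 2 passed without inactive replicate 2 at 4 h. The median difference in LP-1 moved by -0.15 when each array was centred.

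The inactive enantiomer was compared with untreated cells to show the background of the treatment, with the limit that no untreated or vehicle group was taken at 4 or 8 h. In LP-1 HMOX1, the heme-degrading enzyme induced by oxidative stress, rose by 2.36 ± 0.29 at 4 h (5.14-fold, adjusted p = 0.0325) and by 2.58 ± 0.29 at 8 h (5.96-fold, adjusted p = 0.00338). ANXA1, an anti-inflammatory phospholipid-binding protein gene, rose by 2.68 ± 0.34 and 2.66 ± 0.34 (adjusted p = 0.0325 and 0.00952). FTL, the ferritin light chain gene, rose by 1.04 ± 0.18 at 8 h (adjusted p = 0.0376), with a value of 1.13 ± 0.18 at 4 h (adjusted p = 0.159). ALX1, a homeobox gene, fell by 1.27 ± 0.17 and 0.92 ± 0.17. At 8 h OR52A5 also rose (1.44 ± 0.24), and RPS6KA6, ZNF415, MSMO1, an enzyme of sterol synthesis, and ETFRF1 fell by 1.84 ± 0.25, 1.78 ± 0.32, 1.66 ± 0.17 and 1.63 ± 0.31. In all 3 probe sets passed in LP-1 at 4 h and 111 at 8 h (10 higher, 101 lower). With limma 0 passed in Raji at 4 h and 0 at 8 h (1741 and 994 at an unadjusted p under 0.05). MYC stayed within 0.13 of untreated in size: 0.04 (95% interval -0.30 to 0.38) and -0.13 (-0.46 to 0.21) in LP-1, -0.09 (-0.42 to 0.25) and 0.04 (-0.30 to 0.38) in Raji. HEXIM1 lay at -0.18 (-0.48 to 0.12) and -0.26 (-0.56 to 0.04) in LP-1 and at -0.15 (-0.45 to 0.15) and -0.01 (-0.31 to 0.29) in Raji.

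Counts for the inactive enantiomer in LP-1 also moved with single arrays. At 4 h none of the 3 calls was left without any 1 of the 4 arrays. At 8 h the 111 became 24 and 21 without inactive replicates 1 and 2, and 9 and 11 without untreated replicates 1 and 2, with HMOX1 and MSMO1 the 2 of 8 named genes to keep their call throughout. In Raji at 8 h 1 probe set passed without inactive replicate 1. Centring the arrays moved the median change in LP-1 at 8 h by 0.11, left 34 calls and raised the share of higher calls from 9.01% to 29.4%. With only the LP-1 arrays 1 probe set was called at 8 h (1 higher, 0 lower), so MSMO1, which fell, lost its call.

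Setting the BET inhibitor against untreated cells gave the same directions for MYC, HEXIM1 and BRD2, and BRD3 and IRF4 again did not pass. MYC fell by 2.27 ± 0.16 and 1.97 ± 0.16 in LP-1 and by 1.49 ± 0.16 and 1.36 ± 0.16 in Raji at 4 and 8 h, and HEXIM1 rose by 0.86 ± 0.14, 1.20 ± 0.14, 1.79 ± 0.14 and 1.89 ± 0.14. BRD2 rose by 0.59 ± 0.11 and 1.01 ± 0.11 in LP-1 and by 0.58 ± 0.11 and 0.51 ± 0.11 in Raji. HMOX1, which fell against the inactive enantiomer, was above its untreated level in LP-1 with the inhibitor, by 0.35 ± 0.29 at 4 h (adjusted p = 0.549) and by 1.04 ± 0.29 at 8 h (adjusted p = 0.0447). ANXA1 likewise fell against the inactive enantiomer and lay above untreated, by 0.51 ± 0.34 (adjusted p = 0.439) and 1.28 ± 0.34 (adjusted p = 0.0377). In LP-1 1481 probe sets passed at 4 h (160 higher, 1321 lower) and 1685 at 8 h (434 higher, 1251 lower), and in Raji 277 (146 higher, 131 lower) and 498 (230 higher, 268 lower). These comparisons join compound and time in culture. Shares of higher calls moved under centring from 10.8% to 21.3% in LP-1 at 4 h, from 25.8% to 30.9% in LP-1 at 8 h, from 52.7% to 59.5% in Raji at 4 h and from 46.2% to 56.3% in Raji at 8 h. After quantile normalization 734 were higher and 1108 lower in LP-1 at 8 h, and 260 higher and 559 lower in LP-1 at 4 h.

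Leaving out single arrays moved these counts too. For LP-1 at 4 h they were 316 and 2419 without BET inhibitor replicates 1 and 2 and 312 and 440 without untreated replicates 1 and 2. For LP-1 at 8 h they were 1020 without BET inhibitor replicate 1 and 666 and 761 without untreated replicates 1 and 2. In Raji they were 65, 41, 53 and 42 at 4 h and 145, 139, 119 and 79 at 8 h, without BET inhibitor replicates 1 and 2 and untreated replicates 1 and 2 in that order. MYC and HEXIM1 kept their calls in each of these fits. BRD2 kept its call throughout in LP-1 at 8 h alone, with a highest adjusted p of 0.0899 in LP-1 at 4 h and 0.208 and 0.215 in Raji when 1 array was left out.

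Untreated Raji and LP-1 cells, compared to show how the lines differ before treatment, differed in 5342 probe sets (1495 higher and 3847 lower in Raji). The lines were grown in different media, so line and medium cannot be told apart. The genes far higher in Raji include markers of blood cells and B cells: PTPRC, which encodes the leukocyte surface phosphatase CD45, by 6.58 ± 0.17 (adjusted p = 4.72e-11), and CD53 by 7.08 ± 0.22. Also higher in Raji were LCP1 by 6.49 ± 0.16, LAPTM5 by 6.31 ± 0.30, ALOX5AP by 6.44 ± 0.27 and RGS13, a germinal centre B cell gene, by 7.71 ± 0.37, along with COX7A2 (8.72 ± 0.56) and the histone gene H3C11 (7.03 ± 0.46). Lower in Raji were HGF, hepatocyte growth factor, at -8.33 ± 0.26 (adjusted p = 2.14e-10), the cyclin gene CCND2 at -6.58 ± 0.26, TEAD1, a transcription factor of the Hippo pathway, at -7.28 ± 0.33, and GAS2, ITGA8, LRRN1, RDX and PRTFDC1 at -7.05 to -6.55. COX7A2 and TEAD1 each had another probe set, whose difference between the lines is not given here. Their values therefore stand for a single probe set and not for the whole gene. Untreated Raji averaged 2.28 for HGF and untreated LP-1 2.53 for PTPRC, below the 25th percentile of their arrays. No test against background was made, so folds are not given for these genes. IRF4 was lower in Raji (-5.67 ± 0.19) and MYC 2.10-fold lower (-1.07 ± 0.16, adjusted p = 0.000164). Counts without 1 array lay between 3955 and 4199, and all 19 named genes that passed kept their calls. Centring, which moved the median by 0.13, raised the share of higher calls from 28% to 41.2%.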

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

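The differences below were found by planned tests of the response in Raji minus the response in LP-1 to the BET inhibitor over its inactive enantiomer. They drew attention because the effect differed between the lines, which were also grown in different media. At 4 h 25 probe sets differed and at 8 h 54.

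At 4 h the difference in log2 change was 2.63 for NFIL3, 2.26 for RGL1, 2.23 for TUBD1, 1.89 for CA13, 1.67 for LRP2BP and 1.61 for IL12A, each higher in Raji relative to LP-1. It was -1.05 for ATF3, whose rise was in LP-1. None of these 7 calls outlasted the omission of each array in turn. The count at 4 h was 484 without LP-1 BET inhibitor replicate 2 and 0 without LP-1 inactive replicate 2, with 8, 1, 2, 2, 11 and 15 without LP-1 BET inhibitor replicate 1, LP-1 inactive replicate 1, Raji BET inhibitor replicates 1 and 2 and Raji inactive replicates 1 and 2.

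At 8 h the difference was 3.25 for CCR1, 2.32 for PECAM1, 2.19 for SELPLG, 1.93 for EDNRB and 1.81 for MLKL, all of which fell in LP-1, and 2.01 for GPRC5D, which fell in LP-1 and rose in Raji. It was -2.72 for FGD6, -2.46 for CEMIP2, -2.32 for ATP1B1, -2.28 for TUFT1 and -2.16 for PAG1, all of which rose in LP-1, and -2.34 for SPARCL1, which fell in Raji. Levels were not tested against background, and a gene weakly expressed in either line could fall little there.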

How the results depend on the processing

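Leaving out both arrays that stood apart (LP-1 BET inhibitor replicate 1 and Raji inactive replicate 1, both at 4 h) was chosen after the data were seen, and every other alternative was planned. Of 251 named calls, 2054 of 2770 values over the alternatives kept direction and call, 716 lost the call and 0 changed direction. Of 58 named values that did not pass, 3 of 706 passed under an alternative. Replicate numbers are not stated to mark a shared day, and the replicates of 1 number shared little (r of their deviations between groups -0.035 to 0.121 in LP-1 and -0.16 to 0.051 in Raji). An intensity trend with robust variances left every count within 1.5 times its value. Signal near the lower end of the scale limits falls of weakly expressed genes.

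Leaving out single arrays moved the counts of BET inhibitor over inactive enantiomer to 64 to 971 (LP-1 4 h), 485 to 985 (LP-1 8 h; 485 to 592 among omissions that moved it), 27 to 154 (Raji 4 h) and 100 to 145 (Raji 8 h). For BET inhibitor over untreated they were 312 to 2419, 666 to 1142 (666 to 1020 among omissions that moved it), 41 to 65 and 79 to 145 in the same order. For inactive enantiomer over untreated they were 0 to 0 in LP-1 at 4 h, 9 to 24 in LP-1 at 8 h and 0 to 1 in Raji at 8 h. Differences between lines ranged from 0 to 484 at 4 h and 17 to 131 at 8 h, differences between times from 0 to 560 in LP-1 and 0 to 2 in Raji, and r between the lines' responses from -0.041 to 0.097 at 4 h and 0.207 to 0.23 at 8 h. Fewer arrays give fewer residual degrees of freedom. The cause of the rises on omission was not tested.

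With only the arrays of the line concerned, which leaves 5 residual degrees of freedom in place of 10, the counts of BET inhibitor over inactive enantiomer were 76, 347, 49 and 90 (LP-1 4 and 8 h, Raji 4 and 8 h), those over untreated 379, 775, 67 and 148, and those of inactive enantiomer over untreated 1 in LP-1 at 4 h and 1 at 8 h. An estimated correlation left 5, 4, 2 and 4 of the 9, 11, 12 and 14 lists. The correlations estimated for most lists exceeded the preset value. Their size alone does not account for the higher p-values. For the MYC network in Raji at 4 h the estimate was -0.0158, below the preset, and camera's p still rose from 0.143 to 0.152.

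Without the 7337 probe sets of lowest mean, inactive enantiomer over untreated in LP-1 at 4 h gave 1, differences between lines at 4 h gave 104, and r between the lines' responses was 0.128 at 4 h and 0.405 at 8 h. Quantile normalization gave 819 (LP-1 4 h), 470 (Raji 4 h) and 757 (Raji 8 h) for BET inhibitor over untreated, 1 and 19 for inactive enantiomer over untreated in LP-1 at 4 and 8 h, 16 for lines at 4 h and 5 for times in Raji. Centring gave 983 for BET inhibitor over untreated in LP-1 at 4 h, 34 for inactive enantiomer over untreated in LP-1 at 8 h and 4 for lines at 4 h. The replicate block gave 0 and 51 for inactive enantiomer over untreated in LP-1 at 4 and 8 h, and 7 and 34 for lines at 4 and 8 h. Without the arrays that stood apart, BET inhibitor over inactive enantiomer gave 143 (LP-1 4 h) and 148 (Raji 4 h), BET inhibitor over untreated 324 (LP-1 4 h), inactive enantiomer over untreated 0 and 241 in LP-1 at 4 and 8 h and 1 in Raji at 8 h, times in Raji 3, lines at 4 h 10, and r at 4 h 0.108. For the values in this paragraph, the cause was not tested.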

Other observations

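Tests chosen after the result was seen were those on a single array, on scaling, on both together, on time in culture and on probes that also bind histone transcripts. The others were set down first, with limits on the value. To count in favour, NRF2 targets and histone gene neighbours also needed a camera p under 0.05 with an estimated correlation. Verdicts below also weigh omissions of an array or a bootstrap interval, which were not part of those limits. By value alone, a trend with brightness, other NRF2 targets and histone gene neighbours in LP-1 at 4 h would have been argued against. They are left open below.

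Several genes outside the named groups, chosen after their values were seen, changed in one direction in both lines at both times. POLR2A, which encodes the large subunit of RNA polymerase II, rose by 0.69, 1.53, 1.31 and 1.27 (LP-1 at 4 and 8 h, Raji at 4 and 8 h), CSRNP2 by 1.23, 1.74, 1.72 and 1.36, and MKNK2, a kinase that phosphorylates the translation factor eIF4E, by 0.61, 1.26, 0.90 and 0.68. ALKBH8, a tRNA-modifying enzyme gene, fell by 1.63, 2.03, 1.20 and 1.36, UTP25, which serves ribosome assembly, by 1.59, 1.25, 0.91 and 0.88, and ZMYND8, which encodes a reader of acetylated histones, by 0.95, 1.06, 0.97 and 0.94. With each of 16 treated arrays left out in turn, POLR2A, CSRNP2 and ALKBH8 stayed called in all 4 comparisons in 13 cases, ZMYND8 in 10, UTP25 in 9 and MKNK2 in 6.

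In LP-1 most calls of BET inhibitor over inactive enantiomer were lower at 4 h and higher at 8 h, by shares of higher calls that lay 49.1 percentage points apart, although 0 probe sets passed the test of a change between times (2901 at an unadjusted p under 0.05). Centring each array left 23.5 points and cyclic loess, which removes trends with brightness, 24.4, and neither decides, as gaps with 1 array left out ran from -5.2 to 35.5 with centring and from 4.7 to 31 with loess (29 to 59 as deposited). Without the first BET inhibitor array at 4 h, which gave each of these lowest gaps, 37.6% of calls at 4 h were higher as deposited. That array together with centring gave -5.2 points, but it was picked after the gaps were seen and centring without inactive replicate 1 at 8 h also left 9.5 points, so this stays open. A difference in timing of the response stays open too, untested by these values.

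HMOX1, ANXA1 and, at 8 h, FTL rose with the inactive enantiomer over untreated LP-1 cells. RNA from Raji cells is argued against. The 200 probe sets highest in Raji changed by a median of 0.028 at 8 h and -0.013 at 4 h. A bootstrap over these probe sets, which leaves out the spread between arrays, gave 0 to 0.102 at 8 h. Untreated Raji also had less HMOX1 (4.30) and ANXA1 (2.48) than untreated LP-1 (7.66 and 4.28). An oxidative stress response that takes in other targets of the transcription factor NRF2 stays open: the median of 21 such genes was 0.057 at 4 h (-0.032 to 0.138) and 0.003 at 8 h (-0.102 to 0.118), with members from UGDH (-0.42 and -0.75) to SRXN1 (0.61 and 0.49), none called, and in Raji at 8 h, where HMOX1 was not called, the median was 0.164 (-0.039 to 0.237); camera gave p = 0.00176 at 4 h with the preset and p = 0.0932 with an estimated correlation. Compound and time in culture or handling cannot be told apart, because 0 untreated or vehicle groups were taken at 4 or 8 h. FTL rose further with the BET inhibitor, by 0.99 and 1.31 over the inactive enantiomer, whereas HMOX1 and ANXA1 fell. The median of the 21 NRF2 targets was -0.138 at 4 h and 0.232 at 8 h in that comparison (all genes -0.035 and 0.07). Of the 21, 0 were called higher and 1 lower at 4 h, and 5 higher and 0 lower at 8 h. Camera gave p = 0.643 and p = 0.00781 with the preset, and p = 0.789 and p = 0.146 with an estimated correlation.

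OR2B6, an olfactory receptor gene that lies among histone genes, was called higher in all 4 comparisons. Of the 22 genes of the histone list 2, 6, 2 and 1 were called higher (LP-1 at 4 and 8 h, Raji at 4 and 8 h), with H2BC11 alone in all 4. OR2B6 kept all 4 calls in 5 of 16 omissions of an array, and in Raji at 8 h lost its call without any 1 array. A general rise of genes beside histone genes is argued against in LP-1 at 8 h and in Raji. There the median of 44 neighbours of any histone gene exceeded that of all genes by at most 0.006 (highest upper bound 0.076). These bounds come from a bootstrap over the genes, which leaves out the spread between arrays. Such a general rise stays open in LP-1 at 4 h (-0.001, interval -0.071 to 0.201). A median over all these neighbours cannot decide on a rise of a few genes near OR2B6, which stays open in each comparison. Its neighbouring paralogue OR2B2 changed by 2.19 (adjusted p = 0.0587) and 2.42 (adjusted p = 0.0212) in LP-1 and by 0.36 and 0.03 in Raji, and in LP-1 at 8 h HFE was also called higher (0.66) but BTN3A2 (-1.29) and RRP1B (-0.52) lower. Probes that also bind histone transcripts stay open: OR2B6 differed from the histone gene that rose most, of 54, by 0.90, 0.02, 0.75 and -0.06 (LP-1 at 4 and 8 h, Raji at 4 and 8 h), by over 2 standard errors in 0 of 4, and in Raji the control levels of OR2B6 and of H2BC11, the histone gene that rose most, lay below the 25th percentile of their arrays. A shared regulation of the locus is a hypothesis that the design does not test.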
